A study of Sus scrofa with 18 samples.

How the data were processed

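RNA of 18 pig kidneys was hybridised to an Affymetrix pig array, 1 array per kidney. The values are log2 summaries per probe set that the authors normalised between arrays with RMA before they were deposited, per the labels, which give neither the version nor the settings. The range of 0.226 to 13.46 and the array medians of 3.753 to 3.943 match a log2 scale, and no value was missing. Arrays have no counts, so their number limits the precision. Background was taken as 1.65, from 17 tag control probe sets.

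Arrays were grouped by source and title into naive (n = 2), untreated 4 h, untreated 24 h, CO 4 h and CO 24 h kidneys (n = 4 each). The treatment field of the CO arrays reads air, and the source and title, which name CO, were followed. Whether donor, graft or recipient received CO is not stated. Numbers in the file names of both naive arrays recur in those of both donor 4 arrays, so naive kidneys may share animals with that pair, which the tests ignore. Batches were read from the array file names: batch 1 holds naive 1 and both groups of donors 1, 3 and 4, batch 2 holds naive 2, both kidneys of donor 2 and the untreated kidney of donor 5, batch 3 holds the other 24 h arrays except CO donor 6, and batch 4 holds that array. Donor numbers pair the CO and untreated groups, but the pairing could be checked in part only: after group means were removed, the partner array had the highest correlation in 4 of 8 donors.

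Of 24123 probe sets, 124 controls were left out and 23999 tested with no filter. The platform annotation gives 10069 of them 1 gene symbol, 198 several and 13732 none. Of these, 9961 matched a gene of the Sscrofa11.1 annotation by identifier and 6765 distinct genes were named.

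The design, lists, named genes and most alternatives were chosen before the data were examined. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 18 arrays, no block), two-sided, with a Benjamini-Hochberg adjusted p under 0.05. Comparisons were each transplanted group against naive, CO against untreated at each time, over both and between them, and 24 h against 4 h. Named genes are, first, the 8 largest rises and 8 largest falls with 1 symbol that passed and whose groups did not overlap, or the 10 of smallest p where under 10 passed. Second come 16 genes fixed in advance, of which 11 were measured, with HSP70.2 standing for HSPA1A. Last come from each list up to 3 members that passed with the largest change, or else the member of smallest p. These are shortened for the time comparisons and for the difference between times. Errors after ± are standard errors from limma unless SD is stated.

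Of 808 list entries in 25 lists, 540 were measured. Lists of at least 5 measured genes were tested with camera at a preset correlation of 0.01, with the brightest probe set of each gene, and adjusted over 24 lists. The glomerular list had only WT1, TCF21 and VEGFA measured and was not tested. With estimated correlation, 0 of the calls in any comparison held. Camera p values without 1 array, added after the data were seen, are given where the call changed, for CO against untreated where it ended. Endoplasmic reticulum is shortened to ER. A list's score is the mean log2 level of its genes above the naive mean. The transplantation score is the mean of probe sets higher minus the mean of those lower, at most 200 each way, in the untreated comparison at the other time, tested by exact permutation.

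Alternatives were variance model, filter, normalisation, array weights, batch and donor as blocks (statmod 1.5.0), fewer groups in the fit and leaving out arrays, with fry and an estimated correlation for lists. On simulated data with 200 changed probe sets, limma found 0% to 12% of log2 changes of 0.5, 34% to 74% of those of 1, 70% to 94% of those of 1.5 and 86% to 98% of those of 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.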

Results

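Messenger RNA was measured on 18 Affymetrix pig arrays, each hybridised with RNA from 1 kidney. The series is about injury of transplanted kidneys when blood flow returns (ischemia and reperfusion) and about carbon monoxide (CO). Naive kidneys, which were not transplanted, had 2 arrays. Transplanted kidneys were sampled at 4 h or 24 h, untreated or with CO, with 4 arrays in each of these 4 groups. Donors 1 to 4 gave the kidneys of the 4 h groups and donors 5 to 8 those of the 24 h groups, so each donor number has 1 untreated and 1 CO kidney. Numbers in parentheses after a gene are log2 changes unless said otherwise, for lists the adjusted p is that of camera, and "at least" folds stand where the level of 1 group was below background (1.65).

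Arrays separated first by time and then by transplantation. The first principal component, with 36.5% of the variance, put the arrays of 24 h kidneys between 15.1 and 60, and the naive and 4 h arrays between -66.7 and -10.9. The second, with 23.2%, put the naive arrays at 71 and 69.2. The array of the untreated 4 h kidney of donor 1 stood nearest to them, at 49.7, while the other untreated 4 h arrays lay between -41.8 and -9.52. That array had a mean correlation of 0.982 with the naive arrays and of 0.956 with its own group.

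**Figure D1:**
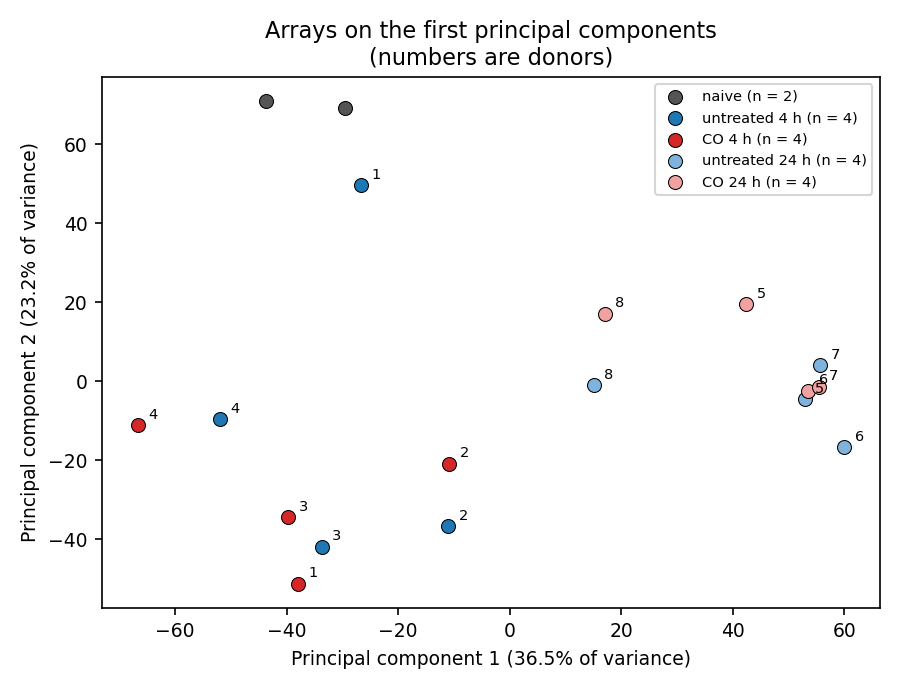
Each point is 1 of the 18 arrays, placed by its scores on the first and second principal components of all tested probe sets (36.5% and 23.2% of the variance). Numbers are donors, and the untreated 4 h array of donor 1 lies at 49.7 on the second.

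What transplantation without CO did by 4 h was asked by comparing the untreated 4 h kidneys (n = 4) with the naive kidneys (n = 2). TNFRSF12A, the receptor of the cytokine TWEAK and induced in injured tubules, had the largest rise among named genes that passed (4.56 ± 0.67, adjusted p = 0.0133). MMP7, a matrix protease of injured tubules (3.88 ± 0.80, adjusted p = 0.0354), and CDKN1A, a p53-regulated inhibitor of the cell cycle (2.87 ± 0.54, adjusted p = 0.0257), rose with it. THBD, the endothelial receptor of thrombin (3.03 ± 0.48, adjusted p = 0.0172), and the adhesion molecule ICAM1 (2.01 ± 0.45, adjusted p = 0.0405) also rose. ATP6V1C2 (-3.13 ± 0.73, adjusted p = 0.0473) and ATP6V0A4 (-2.16 ± 0.46, adjusted p = 0.0358), subunits of the proton pump that acidifies urine, fell.

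In limma, 361 of 23999 probe sets passed an adjusted p under 0.05, 226 higher and 135 lower, and 4973 had an unadjusted p under 0.05. The named genes with the largest rises were TNFRSF12A (4.56), GPRC5A (3.92), MMP7 (3.88), THBS1 (3.16), SLN (3.08), THBD (3.03), SRGN (2.88) and CDKN1A (2.87). Those with the largest falls were ATP6V1C2 (-3.13), NAP1L3 (-2.34), MFAP5 (-2.25), ATP6V0A4 (-2.16), TMEM100 (at least 2.55-fold lower), NUDT2 (-1.68), RWDD3 (-1.60) and C14H10orf35 (-1.53). Standard errors of the named genes ran from 0.17 to 1.083, and adjusted p values of those past the threshold from 0.0133 to 0.0496. Among genes fixed beforehand, ICAM1 (2.01) passed the test. The values that did not pass were HMOX1 (1.43), HMOX2 (-0.30), IL6 (at least 1.46-fold higher), CXCL8 (at least 5.01-fold higher), CCL2 (3.495), IL1B (0.75), TNF (-0.08), VEGFA (-0.23), HSP70.2 (2.71) and NOS2 (0.05), where HSP70.2 is the probe set of inducible HSP70.

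Of 21 heat shock genes, 1 rose (15 higher adjusted over the list alone, median 1.54, adjusted p = 4.18e-10, adjusted p = 0.31 with estimated correlation). It was HSP90AA1 (1.67). Of 18 immediate early genes, 3 rose (12 higher adjusted over the list alone, median 1.26, adjusted p = 1.76e-07, adjusted p = 0.31 with estimated correlation). They were MYC (2.64), IER5 (1.95) and DUSP6 (1.27). Of 18 tubular injury markers, 4 rose (13 higher and 1 lower adjusted over the list alone, median 2.01, adjusted p = 1.76e-07, adjusted p = 0.31 with estimated correlation). Among them were MMP7 (3.88), TNFRSF12A (3.17 at its brighter probe set) and CDKN1A (2.87). Of 25 ER stress genes, 3 rose (15 higher adjusted over the list alone, median 0.83, adjusted p = 7.79e-07, adjusted p = 0.31 with estimated correlation). They were CEBPB (2.71), ATF4 (1.99) and DNAJC3 (1.37). Of 25 p53 and apoptosis genes, 2 rose and 1 fell (9 higher and 3 lower adjusted over the list alone, median 0.40, adjusted p = 0.0068, adjusted p = 0.31 with estimated correlation). They were CDKN1A (2.87), GADD45B (1.93) and TP53I3 (-0.95). The array of donor 1 had a heat shock score of 0.03 above naive, against 2.01 to 2.30 for the other 3.

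Of 33 cytokine and adhesion genes, 3 rose (9 higher adjusted over the list alone, median 0.59, adjusted p = 3.24e-06, adjusted p = 0.31 with estimated correlation). They were IL1R1 (2.44), IL4R (2.37) and ICAM1 (2.01). Of 23 interferon-stimulated genes, 1 rose (1 higher adjusted over the list alone, median 0.68, adjusted p = 0.000414, adjusted p = 0.507 with estimated correlation). It was ISG15 (2.28). Of 25 granulocyte and macrophage markers, none passed in limma and 13 had an unadjusted p under 0.05 (11 higher adjusted over the list alone, median 0.94, adjusted p = 1.22e-06, adjusted p = 0.329 with estimated correlation). The smallest p was that of CD163 (2.91). Of 31 extracellular matrix genes, none passed in limma and 9 had an unadjusted p under 0.05 (7 higher adjusted over the list alone, median 0.52, adjusted p = 0.000304, 0.0787 without untreated donor 2, adjusted p = 0.329 with estimated correlation). The smallest p was that of PLAU (3.05). Of 31 fatty acid oxidation genes, none passed in limma and 10 had an unadjusted p under 0.05 (0 adjusted over the list alone, median -0.44, adjusted p = 0.00335, 0.0717 without naive array 1, adjusted p = 0.507 with estimated correlation). The smallest p was that of BDH1 (-0.54). Of 30 TCA and respiratory chain genes, 2 fell (11 lower adjusted over the list alone, median -0.44, adjusted p = 3.24e-06, adjusted p = 0.31 with estimated correlation). They were SDHC (-1.07) and SUCLG1 (-0.71).

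Of 21 antigen presentation genes, 1 rose (1 higher adjusted over the list alone, median 0.34, adjusted p = 0.15, 0.0283 without naive array 2 and 0.018 without untreated donor 4). It was CTSS (1.30). Of 30 proximal tubule genes, 1 rose (1 higher adjusted over the list alone, median -0.52, adjusted p = 0.112). It was CYP27B1 (1.97). Of 25 coagulation and vascular genes, 1 rose (5 higher and 1 lower adjusted over the list alone, median 0.18, adjusted p = 0.0824). It was THBD (3.03). No member of the remaining lists passed in limma, and over all 13 lists without such a member 55 of 267 list places had an unadjusted p under 0.05. Smallest p values in these lists belonged to hypoxia genes (SLC2A3 (2.46), adjusted p = 0.554), NRF2 and heme genes (HMOX1 (1.43), adjusted p = 0.907), complement and acute phase genes (CD55 (at least 3.84-fold higher), adjusted p = 0.0824, 0.0226 without naive array 2, 0.0482 without untreated donor 3 and 0.018 without untreated donor 4), loop and distal nephron genes (KCNJ1 (-1.96), adjusted p = 0.112), cell cycle genes (CKS2 (1.35), adjusted p = 0.207) and lymphocyte markers (IL2RG (1.93), adjusted p = 0.142, 0.0283 without naive array 2). Markers of further cell types gave endothelial markers (NOS3 (1.14), adjusted p = 0.794), stromal markers (TAGLN (1.32), adjusted p = 0.53), erythroid markers (HBM (0.84), adjusted p = 0.17) and adrenal and fat markers (LPL (-0.88), adjusted p = 0.794).

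Single arrays decided this count. It was 3347 without untreated donor 1, a set that held all of the 361, but 6 without naive array 1, 2 without naive array 2, and 13, 14 and 80 without untreated donors 2, 3 and 4, and it was 105 with array batch as a block, as the median change of the called probe sets went from 1.35 to 1.37 and their median standard error from 0.283 to 0.297. With only the compared groups in the fit it was 0 in limma (3960 at an unadjusted p under 0.05, smallest adjusted p = 0.27).

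By 24 h after transplantation without CO (n = 4, against 2 naive arrays), 25 of 30 proximal tubule genes had fallen, and 12 of 18 tubular injury markers, 12 of 23 interferon-stimulated genes and 13 of 25 granulocyte and macrophage markers had risen (as sets, adjusted p = 0.455 each with estimated correlation). MIOX, the proximal tubule enzyme of inositol breakdown (-4.27 ± 0.49, adjusted p = 0.000143), and DPYS, an enzyme of pyrimidine breakdown (-4.96 ± 0.59, adjusted p = 0.00017), fell, as did EGF, a growth factor made by the distal tubule (-4.21 ± 0.60, adjusted p = 0.000481). MMP7 rose by 7.10 ± 0.80, adjusted p = 0.000142. The chemokine CCL2 (4.42 ± 1.08, adjusted p = 0.0123) and the interferon-induced GTPase GBP1 (4.42 ± 0.88, adjusted p = 0.00373) rose too.

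In limma, 3494 probe sets passed, 1629 higher and 1865 lower. The largest rises among named genes were those of MMP7 (7.10), RBP4 (4.79), UBD (4.46), CCL2 (4.42), GBP1 (4.42), CLDN6 (4.29), CCR1 (4.27) and TNFRSF12A (4.24). The largest falls were those of DPYS (-4.96), INMT (-4.85), CYP2A19 (-4.70), TF (-4.496), UPB1 (-4.49), UGT2B31 (-4.37), MIOX (-4.27) and F9 (-4.24). Standard errors ran from 0.148 to 1.518, and adjusted p values of those past the threshold from 0.000142 to 0.0488. Of the genes fixed beforehand, HMOX2 (-1.01), CXCL8 (at least 3.63-fold higher), CCL2 (4.42), IL1B (2.07) and ICAM1 (2.40) passed the test. Values that did not pass were HMOX1 (1.11), IL6 (1 group below background), TNF (0.72), VEGFA (-0.41), HSP70.2 (0.80) and NOS2 (0.25).

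Of 30 proximal tubule genes, 25 fell (27 lower adjusted over the list alone, median -2.83, adjusted p = 2.91e-16, adjusted p = 0.455 with estimated correlation). Among them were MIOX (-4.27), BHMT (-4.20) and SLC22A6 (-3.83). Of 31 fatty acid oxidation genes, 18 fell (21 lower adjusted over the list alone, median -1, adjusted p = 3.09e-10, adjusted p = 0.455 with estimated correlation). Among them were PHYH (-3.05), PDK4 (-2.74) and ACAA1 (-2.43). Of 30 TCA and respiratory chain genes, 9 fell (12 lower adjusted over the list alone, median -0.38, adjusted p = 1.22e-05, adjusted p = 0.455 with estimated correlation). Among them were SDHC (-2.02), SUCLG2 (-1.38) and SDHA (-1.26). Of 13 loop and distal nephron genes, 5 fell (6 lower adjusted over the list alone, median -0.58, adjusted p = 0.00577, adjusted p = 0.455 with estimated correlation). Among them were EGF (-4.21), HSD11B2 (-1.63) and FXYD2 (-1.63). Of 26 NRF2 and heme genes, 5 rose and 6 fell (8 higher and 8 lower adjusted over the list alone, median 0.10, adjusted p = 0.932, mean 0.11 and set test lower). Among them were NQO1 (2.82), MT1A (-2.29) and TXNRD1 (2.02).

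Of 18 tubular injury markers, 12 rose and 1 fell (15 higher and 1 lower adjusted over the list alone, median 2.17, adjusted p = 8.08e-07, adjusted p = 0.455 with estimated correlation). Among them were MMP7 (7.10), SPP1 (3.54) and TIMP1 (3.53). Of 33 cytokine and adhesion genes, 10 rose (13 higher adjusted over the list alone, median 1.16, adjusted p = 1.22e-05, adjusted p = 0.455 with estimated correlation). Among them were CCL2 (4.42), CCL8 (3.19) and CXCL8 (at least 3.63-fold higher). Of 23 interferon-stimulated genes, 12 rose (19 higher adjusted over the list alone, median 1.72, adjusted p = 1.1e-06, adjusted p = 0.455 with estimated correlation). Among them were GBP1 (4.28 at its brighter probe set), IRF1 (3.37) and GBP2 (3.05). Of 21 antigen presentation genes, 9 rose (9 higher adjusted over the list alone, median 1.24, adjusted p = 6.75e-05, adjusted p = 0.455 with estimated correlation). Among them were PSMB10 (2.69), CTSS (2.68) and PSMB8 (2.66). Of 25 granulocyte and macrophage markers, 13 rose (16 higher adjusted over the list alone, median 1.76, adjusted p = 4.86e-05, adjusted p = 0.455 with estimated correlation). Among them were CCR1 (4.27), GP91-PHOX (3.31) and CD163 (3.21). Of 19 lymphocyte markers, 2 rose (0 adjusted over the list alone, median 1.31, adjusted p = 0.0172, 0.0963 without naive array 1 and 0.0693 without untreated donor 7, adjusted p = 0.55 with estimated correlation). They were IL2RG (2.73) and CD3D (1.67).

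Of 28 cell cycle genes, 10 rose (12 higher adjusted over the list alone, median 1.11, adjusted p = 2.26e-05, adjusted p = 0.455 with estimated correlation). Among them were RRM2 (2.90), MCM2 (2.43) and TYMS (1.99). Of 25 ER stress genes, 13 rose and 2 fell (15 higher and 2 lower adjusted over the list alone, median 0.95, adjusted p = 0.00297, adjusted p = 0.455 with estimated correlation). Among them were CRELD2 (2.68), PHGDH (-2.56) and CEBPB (2.47). Of 18 immediate early genes, 3 rose (4 higher adjusted over the list alone, median 0.65, adjusted p = 0.024, 0.178 without naive array 2 and 0.0943 without untreated donor 8, adjusted p = 0.55 with estimated correlation). They were MYC (2.63), IER5 (1.84) and DUSP6 (0.97). Of 24 hypoxia genes, 5 rose (6 higher adjusted over the list alone, median 0.36, adjusted p = 0.0423, 0.0752 without naive array 1 and 0.346 without untreated donor 8, adjusted p = 0.55 with estimated correlation). Among them were SLC2A3 (3.08), LDHA (2.62) and PFKP (1.08). Of 25 p53 and apoptosis genes, 2 rose and 3 fell (4 higher and 3 lower adjusted over the list alone, median 0.36, adjusted p = 0.378). Among them were CASP1 (3.14), CDKN1A (2.40) and TP53I3 (-1.94).

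Of 23 complement and acute phase genes, 3 rose (3 higher adjusted over the list alone, median 0.48, adjusted p = 0.118). They were CD55 (at least 3.42-fold higher), SAA2 (1.14) and CFB (0.64). Of 31 extracellular matrix genes, 5 rose (5 higher and 1 lower adjusted over the list alone, median 0.40, adjusted p = 0.149). Among them were TIMP1 (3.53), ADAMTS1 (3.02) and PLAU (2.68). Of 25 coagulation and vascular genes, 3 rose and 4 fell (4 higher and 4 lower adjusted over the list alone, median 0.41, adjusted p = 0.626). Among them were PLAU (2.68), CTH (-2.23) and ANGPT1 (-2.19). Of 15 endothelial markers, 1 rose and 1 fell (1 lower adjusted over the list alone, median 0.14, adjusted p = 0.839). They were PECAM1 (1.06) and LYVE1 (-0.58). Of 12 stromal markers, 1 rose and 1 fell (2 higher and 2 lower adjusted over the list alone, median 0.42, adjusted p = 0.724). They were ACTA2 (2.05) and MYL9 (-1.005). Of 13 adrenal and fat markers, 2 fell (2 lower adjusted over the list alone, median -0.12, adjusted p = 0.273). They were LPL (-1.57) and HSD3B1 (-0.93). No member passed in limma among heat shock genes (HSPA4 (1.43), adjusted p = 0.267) and erythroid markers (HBM (0.37), adjusted p = 1), and 4 of their 28 members had an unadjusted p under 0.05.

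The count was 159 with array batch as a block, since the 24 h arrays share a batch with naive arrays through 1 array only, as the median change of the called probe sets went from 1.21 to 1.11 and their median standard error from 0.287 to 0.412. It was 903 without naive array 1, 1214 without naive array 2 and 2282 without untreated donor 6.

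**Figure D2:**
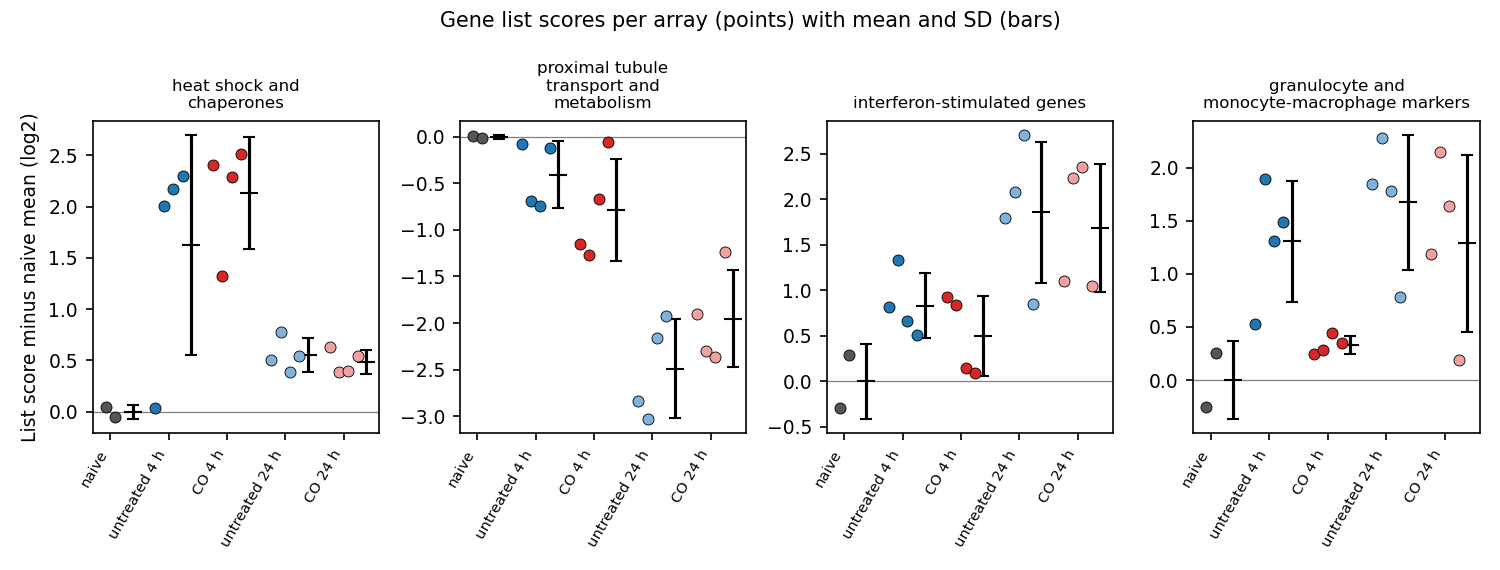
Each point is the mean log2 level of a list's genes on 1 array, minus the naive mean, for 4 lists, and bars give the mean and SD of each group (naive n = 2, others n = 4). Heat shock scores of untreated 4 h kidneys lie between 0.03 and 2.30, and the lowest is that of donor 1.

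With CO, kidneys at 4 h (n = 4) were compared with the naive kidneys (n = 2) for the early response under treatment. HSPA6, an inducible HSP70 (7.25 ± 1.70, adjusted p = 0.0137), and HSPH1, a partner of HSP70 (5.18 ± 1.06, adjusted p = 0.00842), rose. TNFRSF12A (5.49 ± 0.67, adjusted p = 0.00267) and immediate early gene FOSL1 (3.71 ± 0.95, adjusted p = 0.0196) rose. HMOX1, the inducible heme oxygenase, rose no more than without CO (1.36 ± 0.42, adjusted p = 0.0417). CXCL12, a chemokine of stromal cells, fell (-2.55 ± 0.75, adjusted p = 0.035), and so did TCF21, a transcription factor of podocytes and stroma (-2.40 ± 0.45, adjusted p = 0.00646).

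In limma, 3254 probe sets passed, 1641 higher and 1613 lower. Named genes with the largest rises were HSPA6 (7.25), ZFAND2A (5.61), TNFRSF12A (5.49), APOA4 (5.25), HSPH1 (5.18), LIF (at least 23.7-fold higher), DNAJA4 (5.04) and GPRC5A (5.03). Named genes with the largest falls were ATP6V1C2 (-2.97), CXCL12 (-2.55), HECW1 (-2.43), CDH11 (-2.42), TCF21 (-2.40), ITGA8 (-2.35), NAP1L3 (-2.30) and FABP5 (-2.24). Standard errors ran from 0.191 to 1.696, and adjusted p values of those past the threshold from 0.00267 to 0.0486. From the genes fixed beforehand, HMOX1 (1.36), CXCL8 (at least 3.34-fold higher), CCL2 (3.91), ICAM1 (2.22) and HSP70.2 (3.51) passed the test. Not past the threshold were HMOX2 (-0.46), IL6 (at least 1.73-fold higher), IL1B (0.65), TNF (-0.11), VEGFA (-0.35) and NOS2 (0.24).

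Of 21 heat shock genes, 15 rose (19 higher adjusted over the list alone, median 1.91, adjusted p = 1.17e-11, adjusted p = 0.336 with estimated correlation). Among them were HSPH1 (5.18), DNAJB1 (4.16) and CRYAB (3.75). Of 18 immediate early genes, 10 rose (14 higher adjusted over the list alone, median 1.62, adjusted p = 2.11e-08, adjusted p = 0.336 with estimated correlation). Among them were FOSL1 (3.71), FOS (3.45) and MYC (2.95). Of 18 tubular injury markers, 13 rose and 1 fell (14 higher and 1 lower adjusted over the list alone, median 2.53, adjusted p = 2.11e-08, adjusted p = 0.336 with estimated correlation). Among them were MMP7 (4.97), TNFRSF12A (3.99 at its brighter probe set) and CRYAB (3.75). Of 25 ER stress genes, 13 rose (16 higher and 3 lower adjusted over the list alone, median 1.09, adjusted p = 2.66e-06, adjusted p = 0.336 with estimated correlation). Among them were DDIT3 (3.10), ASNS (2.89) and CEBPB (2.76). Of 25 p53 and apoptosis genes, 7 rose and 3 fell (9 higher and 4 lower adjusted over the list alone, median 0.58, adjusted p = 0.0168, 0.0653 without naive array 2, adjusted p = 0.467 with estimated correlation). Among them were CDKN1A (3.39), GADD45B (2.45) and MCL1 (1.495). Of 33 cytokine and adhesion genes, 9 rose and 1 fell (11 higher and 2 lower adjusted over the list alone, median 0.65, adjusted p = 0.000366, adjusted p = 0.521 with estimated correlation). Among them were LIF (at least 23.7-fold higher), CCL2 (3.91) and IL1R1 (2.70).

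Of 30 TCA and respiratory chain genes, 10 fell (1 higher and 18 lower adjusted over the list alone, median -0.56, adjusted p = 1.77e-05, adjusted p = 0.469 with estimated correlation). Among them were SDHC (-1.30), NDUFS3 (-1.27) and NDUFS1 (-0.90). Of 31 fatty acid oxidation genes, 9 fell (10 lower adjusted over the list alone, median -0.56, adjusted p = 0.00759, 0.0565 without naive array 1, adjusted p = 0.758 with estimated correlation). Among them were PHYH (-1.79), ACADS (-1.15) and HADH (-1.09). Of 30 proximal tubule genes, 1 rose and 1 fell (1 higher and 1 lower adjusted over the list alone, median -0.87, adjusted p = 0.00959, 0.105 without CO donor 2, adjusted p = 0.821 with estimated correlation). They were LRP2 (-1.73) and CYP27B1 (1.65). Of 26 NRF2 and heme genes, 4 rose and 1 fell (4 higher and 3 lower adjusted over the list alone, median -0.21, adjusted p = 0.933, mean 0.01 and set test lower). Among them were TXNRD1 (2.63), ME1 (1.40) and BLVRA (-1.37). Of 24 hypoxia genes, 1 rose and 1 fell (1 higher adjusted over the list alone, median 0.23, adjusted p = 0.813). They were SLC16A3 (-1.94) and HIF1A (0.83). Of 31 extracellular matrix genes, 7 rose (8 higher and 1 lower adjusted over the list alone, median 0.07, adjusted p = 0.0606, 0.0403 without naive array 1). Among them were ADAMTS1 (3.77), PLAU (3.24) and TIMP1 (3.05). Of 25 coagulation and vascular genes, 6 rose and 2 fell (8 higher and 2 lower adjusted over the list alone, median 0.24, adjusted p = 0.0606). Among them were THBD (3.56), PLAU (3.24) and PLAT (3.16).

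Of 23 interferon-stimulated genes, 1 rose (1 higher adjusted over the list alone, median 0.41, adjusted p = 0.0606, 0.00864 without naive array 2, 0.0276 without CO donor 3 and 0.0421 without CO donor 4). It was ISG15 (2.01). Of 21 antigen presentation genes, 1 fell (1 lower adjusted over the list alone, median -0.14, adjusted p = 0.895). It was SLA-DMA (-0.84). Of 23 complement and acute phase genes, 2 rose (2 higher adjusted over the list alone, median -0.16, adjusted p = 0.813, mean -0.02 and set test higher). They were CD46 (2.02) and CD55 (at least 3.67-fold higher). Of 28 cell cycle genes, 1 rose (0 adjusted over the list alone, median -0.10, adjusted p = 0.858, mean -0.01 and set test higher). It was CKS2 (1.501). Of 15 endothelial markers, 1 rose (1 higher adjusted over the list alone, median -0.10, adjusted p = 0.835, mean -0.02 and set test higher). It was NOS3 (2.004). Of 7 erythroid markers, 1 rose (1 higher adjusted over the list alone, median 0.30, adjusted p = 0.214). It was BPGM (1.31). Lists without a member past the threshold in limma were granulocyte and macrophage markers (CCR1 (2.44), adjusted p = 0.366), lymphocyte markers (CD27 (1 group below background), adjusted p = 0.933), loop and distal nephron genes (KCNJ1 (-1.85), adjusted p = 0.813), stromal markers (DCN (-1.61), adjusted p = 0.835) and adrenal and fat markers (LPL (-0.82), adjusted p = 0.933), and 10 of their 82 members had an unadjusted p under 0.05.

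The count was 79 without naive array 1 and 1 without naive array 2, and it was 1442 and 1882 without CO donors 1 and 3.

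At 24 h with CO (n = 4, against 2 naive arrays), the proximal tubule genes MIOX (-3.87 ± 0.49, adjusted p = 0.000457) and AQP1, a water channel (-3.82 ± 0.56, adjusted p = 0.000917), fell. MMP7 (6.91 ± 0.80, adjusted p = 0.000411) and the secreted phosphoprotein SPP1 (3.52 ± 0.51, adjusted p = 0.000894) rose, as did MCM2, a helicase subunit of DNA replication (2.65 ± 0.34, adjusted p = 0.000482). HMOX2, the constitutive heme oxygenase, fell (-1.17 ± 0.25, adjusted p = 0.00749).

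In limma, 2804 probe sets passed, 1380 higher and 1424 lower. Largest among the rises were MMP7 (6.91), RBP4 (4.96), CCL2 (4.27), STEAP4 (at least 15.2-fold higher), NPM3 (4.03), TNFRSF12A (3.87), CLDN6 (3.79) and CCR1 (3.71). Largest among the falls were CYP2A19 (-5.10), INMT (-4.29), DPYS (-4.25), MIOX (-3.87), F9 (-3.86), AQP1 (-3.82), UGT2B31 (-3.82) and TF (-3.79). Standard errors ran from 0.179 to 1.518, and adjusted p values of those past the threshold from 0.000411 to 0.0471. Among the genes fixed beforehand here, HMOX2 (-1.17), CCL2 (4.27), IL1B (1.67) and ICAM1 (2.21) passed the test. Genes that did not pass were HMOX1 (0.80), IL6 (at least 1.55-fold higher), CXCL8 (at least 2.83-fold higher), TNF (0.45), VEGFA (-0.63), HSP70.2 (0.47) and NOS2 (0.12).

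Of 30 proximal tubule genes, 18 fell (25 lower adjusted over the list alone, median -2.14, adjusted p = 1.91e-13, adjusted p = 0.565 with estimated correlation). Among them were MIOX (-3.87), SLC22A6 (-3.52) and DPEP1 (-3.40). Of 31 fatty acid oxidation genes, 16 fell (20 lower adjusted over the list alone, median -0.90, adjusted p = 1.59e-09, adjusted p = 0.565 with estimated correlation). Among them were PDK4 (-2.69), PHYH (-2.59) and ACAA1 (-2.05). Of 30 TCA and respiratory chain genes, 6 fell (2 higher and 10 lower adjusted over the list alone, median -0.30, adjusted p = 0.00196, adjusted p = 0.576 with estimated correlation). Among them were SDHC (-1.78), SUCLG2 (-1.32) and SDHA (-0.99). Of 13 loop and distal nephron genes, 5 fell (5 lower adjusted over the list alone, median -0.63, adjusted p = 0.00228, adjusted p = 0.576 with estimated correlation). Among them were EGF (-3.72), HSD11B2 (-1.51) and FXYD2 (-1.36). Of 26 NRF2 and heme genes, 4 rose and 5 fell (5 higher and 7 lower adjusted over the list alone, median 0.08, adjusted p = 0.686, mean 0.06 and set test lower). Among them were NQO1 (2.55), MT1A (-2.38) and CAT (-1.57). Of 18 tubular injury markers, 11 rose and 1 fell (14 higher and 1 lower adjusted over the list alone, median 1.99, adjusted p = 1.33e-06, adjusted p = 0.576 with estimated correlation). Among them were MMP7 (6.91), SPP1 (3.52) and TIMP1 (3.48).

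Of 33 cytokine and adhesion genes, 6 rose (12 higher adjusted over the list alone, median 1.12, adjusted p = 0.000177, adjusted p = 0.576 with estimated correlation). Among them were CCL2 (4.27), CCL8 (2.80) and VCAM1 (2.31). Of 23 interferon-stimulated genes, 9 rose (17 higher adjusted over the list alone, median 1.55, adjusted p = 3.12e-06, adjusted p = 0.576 with estimated correlation). Among them were GBP1 (3.47), ISG15 (2.90) and IRF1 (2.83). Of 21 antigen presentation genes, 6 rose (9 higher adjusted over the list alone, median 0.96, adjusted p = 0.00082, adjusted p = 0.579 with estimated correlation). Among them were PSMB10 (2.31), PSME2 (2.28) and PSMB8 (2.24). Of 25 granulocyte and macrophage markers, 6 rose (12 higher and 1 lower adjusted over the list alone, median 1.52, adjusted p = 0.00228, adjusted p = 0.614 with estimated correlation). Among them were CCR1 (3.71), CD163 (2.95) and GP91-PHOX (2.75). Of 28 cell cycle genes, 11 rose (11 higher adjusted over the list alone, median 1.08, adjusted p = 1.49e-05, adjusted p = 0.576 with estimated correlation). Among them were MCM2 (2.65), RRM2 (2.64) and TYMS (2.11). Of 25 ER stress genes, 13 rose and 2 fell (15 higher and 2 lower adjusted over the list alone, median 0.99, adjusted p = 0.00356, adjusted p = 0.576 with estimated correlation). Among them were CRELD2 (2.55), PHGDH (-2.28) and CEBPB (1.91).

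Of 18 immediate early genes, 3 rose (3 higher adjusted over the list alone, median 0.47, adjusted p = 0.0956, 0.0131 without naive array 1 and 0.0461 without CO donor 5). They were MYC (2.30), IER5 (1.71) and DUSP6 (0.999). Of 24 hypoxia genes, 5 rose (5 higher adjusted over the list alone, median 0.23, adjusted p = 0.198). Among them were SLC2A3 (2.41), LDHA (2.26) and ENO1 (0.98). Of 25 p53 and apoptosis genes, 3 rose and 2 fell (4 higher and 4 lower adjusted over the list alone, median 0.22, adjusted p = 0.678). Among them were CASP1 (2.74), CDKN1A (2.02) and TP53I3 (-1.40). Of 31 extracellular matrix genes, 5 rose (5 higher adjusted over the list alone, median 0.59, adjusted p = 0.127). Among them were TIMP1 (3.48), ADAMTS1 (2.98) and TGFB1 (2.20). Of 25 coagulation and vascular genes, 3 rose and 4 fell (7 higher and 4 lower adjusted over the list alone, median 0.34, adjusted p = 0.678). Among them were PROCR (2.08), CTH (-2.01) and ANGPT1 (-1.69). Of 23 complement and acute phase genes, 1 rose (1 higher adjusted over the list alone, median 0.49, adjusted p = 0.198). It was SAA2 (1.17). Of 15 endothelial markers, 1 rose (1 higher adjusted over the list alone, median 0.21, adjusted p = 0.686). It was PECAM1 (1.24). Of 12 stromal markers, 2 rose (4 higher and 1 lower adjusted over the list alone, median 0.41, adjusted p = 0.414). They were ACTA2 (2.44) and TPM2 (1.95). Of 13 adrenal and fat markers, 1 fell (1 lower adjusted over the list alone, median -0.12, adjusted p = 0.185). It was LPL (-1.57). For heat shock genes (HSPA4 (1.37), adjusted p = 0.293), lymphocyte markers (IL2RG (2.17), adjusted p = 0.18, 0.036 without CO donor 8) and erythroid markers (HBB (-0.25), adjusted p = 0.903), no member passed in limma, and 5 of 47 members had an unadjusted p under 0.05.

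With array batch as a block, linked to naive by untreated donor 5 alone, the count was 0 in limma (2316 at an unadjusted p under 0.05), as the median change of the called probe sets went from 1.19 to 1.08 and their median standard error from 0.281 to 0.479. It was 459 and 743 without naive arrays 1 and 2, and 1731 without CO donor 7.

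Whether CO changed the kidney at 4 h was asked by comparing CO with untreated kidneys (n = 4 each). No gene passed the test, and as a set granulocyte and macrophage markers were lower with CO (median -1.09, camera adjusted p = 1.97e-14). With an estimated correlation that list had adjusted p = 0.472. LAPTM5, a lysosomal membrane protein of leukocytes, had -1.46 ± 0.41, adjusted p = 0.999. The score of the list was lower in the CO kidney in 4 of 4 donors, with a mean difference of -0.98 ± 0.55 (SD), and of -0.77 within the array batch that holds donors 1, 3 and 4. Heat shock genes were higher as a set (median 0.45, camera adjusted p = 1.08e-06), with adjusted p = 0.62 with estimated correlation and 0.583 by camera without untreated donor 1, where the mean went from 0.507 to -0.0244.

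In limma, 0 probe sets passed, and 787 had an unadjusted p under 0.05, where chance alone gives 1200. The named probe sets with the smallest p were ME1 (at least 1.78-fold higher), ACSS2 (-0.78), TSPAN2 (0.67), DDB2 (-0.74), OCLN (0.75), RIPOR2 (-0.77), LAPTM5 (-1.46), ACTG2 (-1.06), LAPTM5 by another probe set (below background in both groups) and MEIS1 (-0.76), with adjusted p = 0.999 for each. Genes fixed beforehand had HMOX1 (-0.07), HMOX2 (-0.16), IL6 (0.24), CXCL8 (-0.58), CCL2 (0.41), IL1B (-0.09), TNF (-0.03), ICAM1 (0.21), VEGFA (-0.12), HSP70.2 (0.80) and NOS2 (0.19). Standard errors ran from 0.099 to 0.885. With donors as a block, 1 probe set passed, that of LAPTM5 (-1.46 ± 0.14, adjusted p = 0.0205, 0.136 with batch too and 0.0611 without donors 1 and 8). Of 25 granulocyte and macrophage markers 12 had an unadjusted p under 0.05 and 6 were lower adjusted over the list alone, with the smallest p for LAPTM5 (-1.46 at its brighter probe set). In each other list 0 passed by either adjustment in limma.

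Further lists are given with the mean, its range without 1 array, the adjusted camera p and the member of smallest p. After the word without stands the adjusted camera p for each array whose absence ended the call, in tests chosen after the data were seen, with U and C for the untreated and CO kidney of a donor. Lower as sets with CO were antigen presentation genes (mean -0.507, -0.734 to -0.347, adjusted p = 0.000155, without C4 0.0903, SLA-DMB (-1.30)), proximal tubule genes (mean -0.379, -0.621 to -0.217, adjusted p = 0.000302, without C2 0.287, ANPEP (-0.73)), lymphocyte markers (mean -0.466, -0.609 to -0.321, adjusted p = 0.00533, without U2 0.171, C4 0.118, CD27 (1 group below background)) and stromal markers (mean -0.46, -0.644 to -0.0825, adjusted p = 0.0126, without U2 0.778, C4 0.297, LUM (-1.87)). So were complement and acute phase genes (mean -0.38, -0.517 to -0.218, adjusted p = 0.02, without U2 0.291, U3 0.0725, C4 0.104, CFD (-1.06)), interferon-stimulated genes (mean -0.332, -0.474 to -0.165, adjusted p = 0.02, without U2 0.464, C3 0.154, C4 0.307, IFIT1 (-0.80)) and extracellular matrix genes (mean -0.302, -0.513 to 0.0504, adjusted p = 0.0251, without U2 0.672, C2 0.124, U3 0.0725, C4 0.242, LUM (-1.87)). Those lists had adjusted p = 0.472 to 0.758 with estimated correlation. Higher as sets were tubular injury markers (mean 0.521, 0.0686 to 0.694, adjusted p = 2.62e-05, without U1 0.247, LGALS3 (1.10)), immediate early genes (mean 0.335, -0.0461 to 0.557, adjusted p = 0.000419, without U1 0.83, KLF4 (0.67)), ER stress genes (mean 0.173, -0.0752 to 0.274, adjusted p = 0.0425, without U1 0.369, C1 0.193, C3 0.0841, C4 0.297, ASNS (1.08)) and loop and distal nephron genes (mean 0.144, 0.0241 to 0.243, adjusted p = 0.0439, without U2 0.421, C2 0.321, U3 0.121, U4 0.067, C4 0.0903, SCNN1A (0.57)), and the smallest p among heat shock genes was that of CRYAB (1.21). Those had adjusted p = 0.62 to 0.699 with estimated correlation. The means of heat shock, immediate early and ER stress genes turned sign without U1, as did that of extracellular matrix genes without U2. Of the sets called at 4 h, only granulocyte and macrophage markers kept their call without each array. No call was made for hypoxia genes (adjusted p = 0.992, HIF1A (0.40)), NRF2 and heme genes (adjusted p = 0.984, ME1 (0.93 at its brighter probe set)), cytokine and adhesion genes (adjusted p = 0.799, IL18 (-1.17)), fatty acid oxidation genes (adjusted p = 0.22, ETFB (-0.31)), TCA and respiratory chain genes (adjusted p = 0.12, NDUFS3 (-0.35)) and cell cycle genes (adjusted p = 0.0797, RRM2 (-1.11)). Nor was there 1 for p53 and apoptosis genes (adjusted p = 0.555, CASP1 (-1.70)), coagulation and vascular genes (adjusted p = 0.192, NOS3 (0.86)), endothelial markers (adjusted p = 0.636, NOS3 (0.86)), erythroid markers (adjusted p = 0.555, KLF1 (1 group below background)) and adrenal and fat markers (adjusted p = 0.797, CYP11A1 (below background in both groups)), but 5 of these 11 had a call without 1 array or another.

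A transplantation score, from the 200 probe sets with the largest rises and the 200 with the largest falls in untreated 24 h against naive kidneys, was -1.12 ± 0.90 (SD) with CO and -1.36 ± 1.20 without. The difference of 0.24 was within the spread between kidneys (exact permutation p = 0.771, two-sided, n = 4 each), and it was -0.252 without untreated donor 1. Within the batch of donors 1, 3 and 4 it was 0.37 (exact permutation p = 0.7), and with donors as a block the exact permutation p was 1.

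At 24 h, CO kidneys (n = 4) had higher levels of proximal tubule genes as a set than untreated kidneys (n = 4), with a median of 0.52 (camera adjusted p = 1.58e-10). The mean was 0.536, and 0.356 without untreated donor 6 and 0.298 without CO donor 8, and the score was lower with CO in 1 of 4 donors. Granulocyte and macrophage markers were lower as a set, with a median of -0.41 (camera adjusted p = 9.18e-07). Without CO donor 8 that call was lost (adjusted p = 0.333, mean from -0.384 to -0.0171). Both lists had adjusted p = 0.681 with estimated correlation, and no gene passed. LRP2, the endocytic receptor megalin of the proximal tubule, had 1.04 ± 0.39, adjusted p = 1, and NCF1, a subunit of the phagocyte oxidase, had -0.72 ± 0.30, adjusted p = 1. The granulocyte score was lower with CO in 4 of 4 donors, with a mean difference of -0.38 ± 0.28 (SD). In batch 3 it differed by -0.143 and -0.594 in donors 7 and 8, and the proximal tubule score by -0.21 and 0.69.

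In limma, 0 probe sets passed and 281 had an unadjusted p under 0.05. No list member passed by either adjustment, over all probe sets or adjusted over the list alone, and 8 of 536 list places had an unadjusted p under 0.05. Probe sets of named genes with the smallest p were PIK3AP1 (-0.66), PTBP3 (-0.79), LOC102160313 (1 group below background), LOC100517674 (0.32), SEPHS2 (0.52), TP53I3 (0.54), SLC17A1 (1.05), EI24 (0.62), TMEM237 (0.44) and PPARA (1 group below background), with adjusted p = 1 for each. Genes fixed beforehand gave HMOX1 (-0.31), HMOX2 (-0.16), IL6 (0.67), CXCL8 (-0.36), CCL2 (-0.15), IL1B (-0.40), TNF (-0.27), ICAM1 (-0.19), VEGFA (-0.22), HSP70.2 (-0.33) and NOS2 (-0.14). Standard errors ran from 0.105 to 0.885. Further sets higher with CO were TCA and respiratory chain genes (mean 0.171, 0.114 to 0.215, adjusted p = 2.41e-08, SUCLG1 (0.28)) and fatty acid oxidation genes (mean 0.184, 0.112 to 0.254, adjusted p = 0.00228, without C8 0.475, PPARA (1 group below background)). Further sets lower were lymphocyte markers (mean -0.372, -0.771 to -0.0473, adjusted p = 8.79e-05, without U7 0.344, C8 0.195, CD27 (1 group below background)), antigen presentation genes (mean -0.24, -0.545 to 0.0511, adjusted p = 0.00096, without U6 0.0885, U7 0.0878, C8 0.562, CTSS (-0.55)), hypoxia genes (mean -0.194, -0.292 to 0.0162, adjusted p = 0.0022, without C7 0.0612, U8 0.664, ERO1A (-0.71)), cytokine and adhesion genes (mean -0.163, -0.374 to 0.0648, adjusted p = 0.0022, without U6 0.0678, U7 0.104, C8 0.546, IL6 (0.67)) and immediate early genes (mean -0.162, -0.26 to -0.0803, adjusted p = 0.0406, without C5 0.419, U6 0.185, C6 0.104, U8 0.485, SGK1 (0.42)). These lists had adjusted p = 0.681 to 0.802 with estimated correlation. Lists without a call were heat shock genes (adjusted p = 0.66, HSPA9 (0.16)), NRF2 and heme genes (adjusted p = 0.317, GPX3 (0.27)), tubular injury markers (adjusted p = 0.127, LGALS3 (-0.60)), complement and acute phase genes (adjusted p = 0.208, ORM1 (-0.58)), interferon-stimulated genes (adjusted p = 0.0614, GBP2 (-0.86)), loop and distal nephron genes (adjusted p = 0.845, PTGER3 (-0.27)) and cell cycle genes (adjusted p = 0.95, MCM3 (0.33)). They also took in p53 and apoptosis genes (adjusted p = 0.126, TP53I3 (0.54)), ER stress genes (adjusted p = 0.527, CEBPB (-0.56)), extracellular matrix genes (adjusted p = 0.879, TIMP3 (-0.54)), coagulation and vascular genes (adjusted p = 0.839, ANGPT1 (0.51)), endothelial markers (adjusted p = 0.738, LYVE1 (0.14)), stromal markers (adjusted p = 0.109, DES (0.39)), erythroid markers (adjusted p = 0.738, HBM (-0.27)) and adrenal and fat markers (adjusted p = 0.581, ADIPOQ (below background in both groups)), and 6 of these 15 had a call without 1 array or another. The mean of hypoxia genes turned sign without U8, and those of antigen presentation and cytokine genes without C8.

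The transplantation score from genes of the 4 h comparison was 1.97 ± 0.17 (SD) with CO and 2.19 ± 0.18 without, a difference of -0.215 (exact permutation p = 0.2, two-sided, n = 4 each). Within the batch of 3 kidneys each it was -0.294 (exact permutation p = 0.2), and with donors as a block the exact permutation p was 0.25, where 4 pairs cannot give a p below 0.125.

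Over both times (n = 8 each), leukocyte genes were lower with CO as sets. Granulocyte and macrophage markers had a median of -0.81 (camera adjusted p = 1.05e-23, adjusted p = 0.14 with estimated correlation). Their score was lower with CO in 8 of 8 donors, by -0.68 ± 0.52 (SD), with an exact sign-flip permutation p = 0.00781 and 0.187 adjusted over the 24 lists. Antigen presentation genes (-0.37 ± 0.34, lower in 7 of 8) and lymphocyte markers (-0.42 ± 0.38, lower in 7 of 8) had exact permutation p values of 0.0156 and 0.0234, each 0.187 after adjustment.

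**Figure D3:**
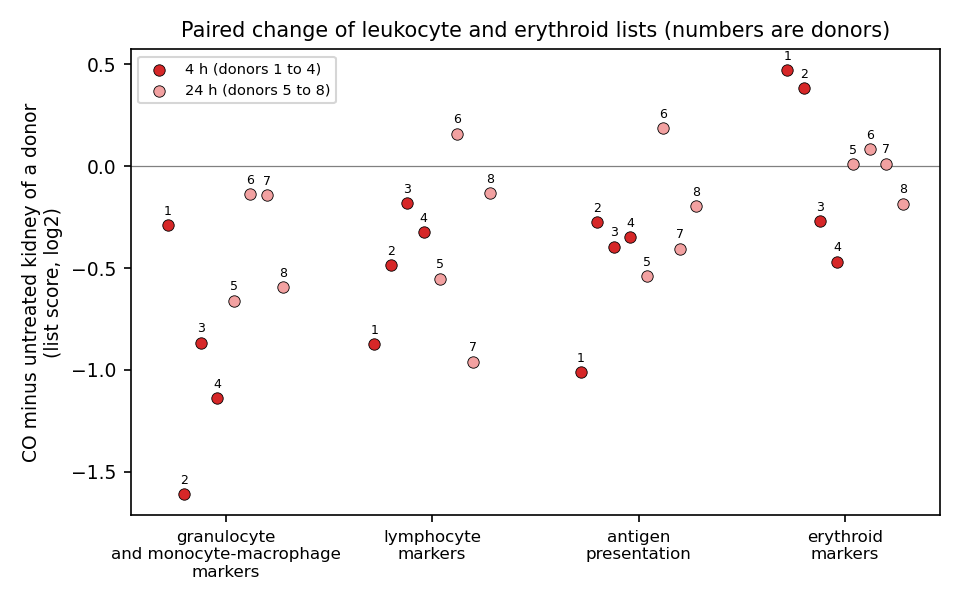
Each point is the score of a gene list in the CO kidney of 1 donor minus that in the untreated kidney of the same donor number (log2), for 4 lists, with donors 1 to 4 at 4 h and donors 5 to 8 at 24 h. For the granulocyte and macrophage list the 8 differences run from -1.61 to -0.14.

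In limma, 0 probe sets passed and 378 had an unadjusted p under 0.05. Named probe sets of smallest p were LAPTM5 (-0.94), VNN2 (-0.65), CTSS (-0.54), ACSS2 (-0.37), CTSS by another probe set (-0.61), ST8SIA4 (-0.43), TSPAN2 (0.38), RIPOR2 (-0.45), RGS18 (-0.45) and NCF1 (-0.64), with adjusted p = 1 for each, and LAPTM5 had the smallest p among granulocyte and macrophage markers. With donors as a block, 1 probe set passed, that of LAPTM5 (-0.94 ± 0.10, adjusted p = 0.0499, 1 with batch too and 0.13 without donors 1 and 8). No list member passed by either adjustment. Fixed genes gave HMOX1 (-0.19), HMOX2 (-0.16), IL6 (0.46), CXCL8 (-0.47), CCL2 (0.13), IL1B (-0.25), TNF (-0.15), ICAM1 (0.01), VEGFA (-0.17), HSP70.2 (0.23) and NOS2 (0.03), and standard errors ran from 0.099 to 0.626. Lower as sets were antigen presentation genes (mean -0.374, -0.526 to -0.228, adjusted p = 1.78e-08, CTSS (-0.54 at its brighter probe set)), lymphocyte markers (mean -0.419, -0.619 to -0.257, adjusted p = 2.52e-07, CD27 (1 group below background)), interferon-stimulated genes (mean -0.253, -0.421 to -0.111, adjusted p = 0.000709, without U2 0.0544, C5 0.168, U7 0.196, IFIT1 (-0.45)), complement and acute phase genes (mean -0.218, -0.286 to -0.137, adjusted p = 0.00292, without U2 0.0642, CFD (-0.68)) and cytokine and adhesion genes (mean -0.134, -0.246 to -0.0205, adjusted p = 0.0291, without U2 0.454, C2 0.107, U3 0.292, C4 0.215, C5 0.0644, U6 0.111, U7 0.124, C8 0.524, IL6 (0.46)). Higher as sets were heat shock genes (mean 0.221, -0.0443 to 0.357, adjusted p = 0.000155, without U1 0.934, HSPA9 (0.18)), tubular injury markers (mean 0.205, -0.0212 to 0.292, adjusted p = 0.0129, without U1 0.668, C1 0.0532, C2 0.0704, C6 0.0868, U7 0.176, KRT8 (0.53)) and TCA and respiratory chain genes (mean 0.0454, 0.00863 to 0.0821, adjusted p = 0.0369, without U2 0.22, U3 0.427, C3 0.0607, C4 0.632, C5 0.212, U6 0.111, U8 0.13, C8 0.187, CYCS (0.23)). These had adjusted p = 0.14 to 0.765 with estimated correlation, and the means of heat shock and tubular injury genes turned sign without U1. No call was made for immediate early genes (adjusted p = 0.133, SGK1 (0.33)), hypoxia genes (adjusted p = 0.0597, HIF1A (0.23)), NRF2 and heme genes (adjusted p = 0.431, ME1 (0.52)), proximal tubule genes (adjusted p = 0.353, SLC5A1 (1.05)), loop and distal nephron genes (adjusted p = 0.133, SCNN1A (0.24)), fatty acid oxidation genes (adjusted p = 0.416, BDH1 (-0.18)) and cell cycle genes (adjusted p = 0.133, RRM2 (-0.69)), nor for p53 and apoptosis genes (adjusted p = 0.673, CASP1 (-1.04)), ER stress genes (adjusted p = 0.257, ASNS (0.49)), extracellular matrix genes (adjusted p = 0.0663, LUM (-0.79)), coagulation and vascular genes (adjusted p = 0.353, NOS3 (0.48)), endothelial markers (adjusted p = 0.431, NOS3 (0.48)), stromal markers (adjusted p = 0.31, LUM (-0.79)), erythroid markers (adjusted p = 0.746, BPGM (0.35)) and adrenal and fat markers (adjusted p = 0.834, ADIPOQ (below background in both groups)), but 11 of these 15 lists had a call without 1 array or another.

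The CO effect at 24 h minus that at 4 h was tested directly. Proximal tubule genes, lower with CO at 4 h and higher at 24 h, had a median difference of 0.93 (camera adjusted p = 3.87e-10, adjusted p = 0.696 with estimated correlation). The score was lower with CO in 2 of 4 donors at 4 h (mean -0.38, exact permutation p = 0.5) and in 1 of 4 at 24 h (mean 0.54, exact permutation p = 0.25). SLC17A1, a phosphate and urate carrier of the proximal tubule, had 1.77 ± 0.51, adjusted p = 0.996, and LRP2 had 1.57 ± 0.55, adjusted p = 0.996. In limma, 0 probe sets passed and 612 had an unadjusted p under 0.05. Of the fixed genes, HMOX1 had -0.24 ± 0.48, adjusted p = 0.996 and HSP70.2 had -1.13 ± 0.997, adjusted p = 0.996. Of 24 lists, 5 had a higher and 3 a lower effect of CO at 24 h by camera, each with adjusted p = 0.696 with estimated correlation.

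Between 4 h and 24 h in untreated kidneys (n = 4 each, from different donors), 22 of 30 proximal tubule genes fell, and 9 of 21 antigen presentation and 4 of 23 interferon-stimulated genes rose. MIOX (-3.77 ± 0.40, adjusted p = 0.000101) and EGF (-3.66 ± 0.49, adjusted p = 0.000411) fell, while NQO1, a target of NRF2 (3.44 ± 0.31, adjusted p = 3.52e-05), and UBD, a ubiquitin-like modifier induced by interferon (4.33 ± 0.60, adjusted p = 0.000549), rose. In limma, 2332 probe sets passed, 1235 higher and 1097 lower at 24 h (1040 and 1210 with each array centred on its median). Of 30 proximal tubule genes, 22 fell (25 lower adjusted over the list alone, median -2.28, adjusted p = 5.37e-21, adjusted p = 0.308 with estimated correlation). Of 21 heat shock genes, 5 fell (9 lower adjusted over the list alone, median -0.80, adjusted p = 6.4e-07, adjusted p = 0.574 with estimated correlation). Of 21 antigen presentation genes, 9 rose (12 higher adjusted over the list alone, median 0.83, adjusted p = 0.000125, adjusted p = 0.574 with estimated correlation). Of 23 interferon-stimulated genes, 4 rose (5 higher adjusted over the list alone, median 0.82, adjusted p = 0.00137, adjusted p = 0.574 with estimated correlation). Among the fixed genes, HMOX2 (-0.71) and IL1B (1.32) passed the test. The count was 1548 without untreated 4 h donor 4, 1320 and 1516 without untreated 24 h donors 6 and 7. Time and array batch overlap but for 1 array, and with batch as a block the count was 0 in limma (1968 at an unadjusted p under 0.05), as the median change of the called probe sets went from 0.943 to 0.825 and their median standard error from 0.215 to 0.366.

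Between 4 h and 24 h with CO (n = 4 each), 15 of 21 heat shock and 7 of 18 immediate early genes fell. HSPA6 (-4.78 ± 1.39, adjusted p = 0.0257) and BAG3, a partner of HSP70 (-4.02 ± 0.62, adjusted p = 0.00072), fell, while KDELR3, a receptor of the secretory pathway (3.83 ± 0.58, adjusted p = 6e-04), and the chemokine CCL8 (3.29 ± 0.63, adjusted p = 0.0025) rose. In limma, 4226 probe sets passed, 2440 higher and 1786 lower at 24 h (2075 and 2179 with each array centred on its median). Of 21 heat shock genes, 15 fell (20 lower adjusted over the list alone, median -1.13, adjusted p = 2.1e-10, adjusted p = 0.497 with estimated correlation). Of 18 immediate early genes, 7 fell (9 lower adjusted over the list alone, median -0.99, adjusted p = 2.2e-05, adjusted p = 0.497 with estimated correlation). Of 30 proximal tubule genes, 15 fell (17 lower adjusted over the list alone, median -1.13, adjusted p = 7.72e-09, adjusted p = 0.497 with estimated correlation). Of 21 antigen presentation genes, 10 rose (16 higher adjusted over the list alone, median 1.27, adjusted p = 4.57e-05, adjusted p = 0.497 with estimated correlation). Of 25 granulocyte and macrophage markers, 8 rose and 1 fell (12 higher and 1 lower adjusted over the list alone, median 0.998, adjusted p = 0.0268, 0.117 without CO 4 h donor 2, 0.167 without CO 24 h donor 6 and 0.0709 without CO 24 h donor 7, adjusted p = 0.696 with estimated correlation). Among the fixed genes, HMOX2 (-0.72) and HSP70.2 (-3.04) passed the test. The count was 2720 without CO 4 h donor 1. No CO array at 24 h shares a batch with 1 at 4 h, so only untreated donor 5 links them, and with batch as a block the count was 0 in limma (2177 at an unadjusted p under 0.05), as the median change of the called probe sets went from 0.897 to 0.836 and their median standard error from 0.213 to 0.435.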

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

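The tests of quality, shares, labels, donors, blood and batch below were chosen only after the results were seen, and the comparison with other splits of the arrays before. Values are listed first where 1 array of 4 lay far from the other 3, by a gap above 0.829 of the group's range, which chance gives in about 1 in 20 groups. This was so in 7 of 40 groups for array measures, 9 of 96 for list scores, 1 of 8 for the transplantation score and 54 of 864 for named genes. The array of untreated 24 h donor 8 had the lowest SD (2.19) and median (3.8) of its group and the highest spike control levels, bioB 7.34, bioC 8.7, bioD 10.5 and cre 12.3, while CO 24 h donor 6 had the lowest bioB, 4.82. List scores that stood apart in untreated 4 h donor 1 were heat shock (0.0329), tubular injury (0.241), p53 (0.0511) and ER stress (0.0922). Others were immediate early genes in CO 4 h donor 2 (1.01), hypoxia (1.15) and fatty acid oxidation (-1.03) in untreated 24 h donor 8, NRF2 and heme genes in CO 24 h donor 5 (0.308), and tubular injury in untreated 24 h donor 7 (1.75). The transplantation score of untreated 24 h donor 6 was 2.66 above the naive mean.

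Log2 levels of named genes that stood apart from the other 3 arrays of a group were, in untreated 4 h donor 1, TNFRSF12A (5.95), CDKN1A (5.03), HSP70.2 (8.31), HSP90AA1 (10.2), ATF4 (7.84), ADAMTS1 (6.77), HSPA6 (2.17), ZFAND2A (3.38), HSPH1 (6.06), DNAJA4 (3.09), FOSL1 (2.42), FOS (5.39), DNAJB1 (7.05), ASNS (5.28), PROCR (2.9) and NFIA (5.62). CO 4 h donor 2 had HSP70.2 (10.9), HSPA4 (7.08), SAA2 (7.12), CD3D (3.68), LYVE1 (2.83), HSPA6 (8.12), DNAJB1 (9.22), ME1 (5.9), LGALS3 (10.9), SLC17A1 (5.5) and EI24 (2.8). In untreated 24 h donor 7 they were GPRC5A (5.64), MMP7 (10.5), DUSP6 (7.75), LPL (3.41), CRYAB (8.4), LGALS3 (7.77) and PTGER3 (4.51). Untreated 24 h donor 8 had CCL2 (7.92), NOS2 (3.47), BDH1 (3.03), CCL8 (3.93), RIPOR2 (1.63) and HSPA9 (9.5). In untreated 4 h donor 2 they were MT1A (7.05), MCM2 (4.76), LAPTM5 (7.86), LAPTM5 by another probe set (2.27) and IL18 (5.34). CO 24 h donor 8 had CD55 (2.79), NPM3 (6.06) and VCAM1 (8.37). Others were DPEP1 (9.87) and ORM1 (5.38) in untreated 4 h donor 4, CD46 (8.51) in CO 4 h donor 4, KLF1 (1.76) in CO 4 h donor 3, KRT8 (9.11) in CO 24 h donor 7 and CA9 (3.08) in untreated 4 h donor 3.

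By direct test, the CO effect at 24 h minus that at 4 h differed in 8 lists. Medians were -0.535 for immediate early, -0.362 for heat shock, -0.581 for tubular injury, 0.932 for proximal tubule and 0.32 for fatty acid oxidation genes. They were 0.256 for TCA and respiratory chain genes, 0.507 for granulocyte and macrophage markers and 0.603 for stromal markers, each with adjusted p = 0.696 with estimated correlation. Without 1 array, in tests chosen after the data were seen, calls ended for immediate early and heat shock genes (without U1 0.0689 and 0.452). Their means shrank to -0.116 and -0.0399, and that of tubular injury from -0.632 to -0.18. Calls ended too for fatty acid oxidation (without U1 0.158, C2 0.103, U4 0.0933, C8 0.221) and stromal markers (U2 0.181, C4 0.154, U7 0.05). So did that for granulocyte and macrophage markers (without U2 0.131, C6 0.237, C7 0.0585, U8 0.109).

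The untreated 4 h array of donor 1 lay close to the naive arrays, and the count against naive was 3347 without it and 361 with it. Poor array quality is argued against, since 1 of 8 quality measures, the highest tag control (1.39 against 1.40 to 1.83), lay outside the range of the other 17 arrays. A naive kidney under a wrong label stays open, as the transplantation score was 0.979 above the naive mean, or 1.14 pooled SD under a bound of 2 SD (other 4 h arrays 1.48 to 3.68), but the SD of 0.862 comes mostly from transplanted kidneys and makes that bound wide. Its interferon score of 0.814 lies with the other untreated 4 h arrays (0.511 to 1.33) and above both naive arrays (-0.291 and 0.291), but 2 arrays do not bound the range of naive kidneys. A sample like naive kidney with a fixed small share of responding tissue stays open. Median shares were 0.00295 over 10 heat shock and 0.0458 over 101 other genes (permutation p = 0.163, Mann-Whitney p = 0.0723). Both tests take genes of 1 array as replicates and cannot decide. A kidney that responded less or later is a biological explanation not tested.

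Granulocyte and macrophage markers were lower in the CO kidney of 8 of 8 donors (mean -0.68, SD 0.52). Erythroid markers (7 genes) differed by 0.00439 (SD 0.316), lower in 3 of 8 donors, and gave no sign of less residual blood. So few genes leave it open. Array batch is argued against by 6 pairs within 1 batch (mean -0.774). All 6 being lower follows from 8 of 8. Chance over donors stays open: the exact permutation p of 0.00781 is the smallest that 8 pairs can give and is 0.187 adjusted over 24 lists. Fewer leukocytes in CO kidneys, or less expression per cell, might each give the pattern and were not told apart by a test.

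Changes between 4 h and 24 h and array batch cannot be told apart, since 1 array of 24 h lies in a batch of the 4 h arrays. With batch as a fixed block, the median change of calls kept 0.874 of its size in untreated and 0.932 in CO kidneys. The latter rests on untreated donor 5 alone. Calls ended as the error grew. A random block (correlation -0.00595) kept nearly all calls, but cannot part batch from time either. Donors also differ between the times, which was not tested.

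Other splits of the same arrays into equal groups were counted. For untreated 24 h against 4 h, 1 of 35 splits, the real 1, gave 2332, and the next 631. For CO 24 h against 4 h 1 of 35 gave 4226, and the next 271. Ranking first of 35 bounds chance at 1 in 35 only, and batch stays open. For the CO comparisons (at 4 h, at 24 h, over both times and for the difference) the real count was 0 in limma, the lowest possible, so every split gave as many (35, 35, 100 and 100) and chance cannot be excluded by them. At an unadjusted p under 0.05 it was 787, 281, 378 and 612. By adjusted p other splits gave up to 86, 4, 3 and 25, above the real 0. Those that part as many donor pairs as the real 1 (8, 8, 6 and 6) gave 0. The 86 point to structure among the 4 h arrays, of untested source.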

How the results depend on the processing

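The fits without the arrays of lowest weight (untreated 4 h donor 1 and untreated 24 h donor 8) or without both arrays of donor 1, the list tests without untreated 4 h donor 1 or without each array in turn, and the donor block without donors 1 and 8 were chosen only after the data were seen, and the others before. Arrays left out 1 at a time are those of the compared groups. Without untreated 4 h donor 1, the counts of comparisons it is not in were 4185 (untreated 24 h against naive), 4146 (CO 4 h), 3486 (CO 24 h) and 4860 (CO 24 h against 4 h). For untreated 4 h against naive (361), the count was 679 in the upper part of probe sets by mean, where fewer are tested, 4760 with array weights, 105 with batch as a block and 0 in limma with only the compared groups in the fit (3960 at an unadjusted p under 0.05). It was 3644 without the arrays of lowest weight and 3296 without both arrays of donor 1. Leaving out 1 array gave 2 to 3347. For untreated 24 h (3494), it was 7744 with weights and 903 to 4197 without 1 array. With batch as a block it was 3534 if random and 159 if fixed. For CO 4 h (3254), it was 7037 with weights and 1 to 3923 without 1 array. For CO 24 h (2804), it was 6224 with weights and 459 to 2970 without 1 array. With batch as a block it was 2827 if random and, if fixed, 0 in limma (2316 at an unadjusted p under 0.05). For untreated 24 h against 4 h (2332), it was 4978 with weights, 0 with batch as a block in limma (1968 unadjusted), 1462 with only those groups and 1320 to 2928 without 1 array (1548 without 4 h donor 4, 1320 and 1516 without 24 h donors 6 and 7). For CO 24 h against 4 h (4226), it was 6934 with weights, 0 with batch as a block in limma (2177 unadjusted) and 2720 to 4781 without 1 array (2720 without 4 h donor 1).

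For CO against untreated the count was 0 in limma (787, 281, 378 and 612 at an unadjusted p under 0.05), and 0 without any 1 of the compared arrays. Exceptions were the donor block, with 1 lower at 4 h and 1 over both times (LAPTM5 each time, 0 with batch too or without donors 1 and 8), and 1 lower at 4 h without the arrays of lowest weight, VCAN (-2.28, adjusted p = 0.0391, and -1.52 with all arrays), named after its values were seen. The transplantation score difference lay between -0.252 and 0.647 without 1 array at 4 h, so its sign is open, and between -0.271 and -0.127 at 24 h.

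Over all comparisons, 300 values of named genes lost their call with batch as a block, 75 with only the compared groups and 782 over the fits that each left out 1 array. Quantile normalisation again ended 17 calls and centring 12, and neither moved the median of all probe sets by more than 0.0876 in size. Which direction had more calls was not stable: centring gave 1546 higher and 1629 lower for CO 4 h (1641 and 1613 without), and weights gave 2256 and 2504 for untreated 4 h (226 and 135), 4034 and 3710 for untreated 24 h (1629 and 1865) and 3193 and 3031 for CO 24 h (1380 and 1424). No named gene or called list turned sign past the threshold. With estimated correlation all 103 list calls were lost, with fry 64 and with donor block 3 (5 gained). Leaving out 1 array at a time ended list calls 108 times and brought them 112 times, and for cell cycle genes in CO against untreated at 24 h it brought calls in both directions (lower without CO donor 5, adjusted p = 3.9e-08, higher without CO donor 8, adjusted p = 0.000438). Causes not stated here were untested. Probe sets with a mean below 1.65, 20.2% of those tested, lie within background, where a change is a lower bound or has no value.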

Other observations

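No explanation was tested in this part. The list of glomerular markers had too few measured genes for a set test. TCF21, a transcription factor of podocytes and stroma, fell in CO 4 h kidneys against naive (-2.40 ± 0.45, adjusted p = 0.00646, n = 4 against 2). It did not pass in untreated 4 h (-1.60, adjusted p = 0.0697), untreated 24 h (-0.80, adjusted p = 0.273) or CO 24 h kidneys (-0.64, adjusted p = 0.419). WT1 did not pass in any of these.

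The spike control bioB was 5.52 ± 0.47 (SD) in CO 24 h and 6.5 ± 0.27 in CO 4 h arrays, a difference of -0.985 (exact permutation p = 0.0286, not adjusted over the measures tested), and 6.56 ± 0.30 in naive arrays (-1.04, exact permutation p = 0.0667 against CO 24 h).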
